A study of Arabidopsis thaliana with 4 samples.

How the data were processed

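RNA of whole 10-day-old seedlings was analysed on 4 Affymetrix ATH1 arrays, 2 of Col and 2 of ref6-1. Per the labels' protocols, biotin-labelled cRNA was made from 10 ug of total RNA extracted with Trizol, and per the series' design text the arrays were run by a service facility. The deposited values are one intensity per probe set and array, made by the authors on a linear scale. The summarization, background correction and normalization behind these intensities are not given in the sources used here. The values themselves had nearly equal medians and upper percentiles on the 4 arrays, as scaling to each other before deposit would give. Their lowest value was 1, which 10, 10, 16 and 17 probe sets held on the 2 Col and the 2 ref6-1 arrays, as a floor would give. Scaling that makes arrays alike can hide a change shared by most genes. Each of the 4 columns was matched to its sample through the labels.

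The table holds 22810 probe sets. The 64 control probe sets were left out of the main test, which covered 22746, and were tested in a separate fit over all 22810, adjusted over these. Intensities were taken as log2(intensity + 16), so fold changes of dim probe sets are understated, and no further normalization or filter was applied. ref6-1 was compared with Col in limma 3.58.1 (R 4.3.3; lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. All adjusted p-values of single genes are limma's. The median total degrees of freedom were 9.80, most of which come from the spread shared across probe sets, and the median SE of a log2 fold change was 0.107. Names came from the platform annotation given for the array, and from the RefSeq gene table of assembly TAIR10.1. A single gene was named for 13513 probe sets, several for 503, and 8730 were not listed. Of the first, 13436 matched a locus, at 13286 loci. The array's genome build is not given in the sources used here, so no coordinates are printed.

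The genes named in the text were fixed by a rule written before the data were examined. It takes the 15 highest and 15 lowest log2 fold changes among probe sets past the threshold with a single gene and both ref6-1 arrays beyond both Col arrays. It adds REF6, which is not named in the annotation used, and from each of 21 fixed gene lists up to 4 members past the threshold or, where fewer than 2 pass, those with the smallest unadjusted p up to 2. Of the 268 list members 28 were named, and 9 others were left out because code and symbol disagreed in the tables. The planned list test needs at least 5 members and could not be run on any of the 21. A further 56 lists, 55 of them with at least 5 loci, were drawn from the symbols in the annotation after the files had been opened but before any expression test. They were tested with camera (preset correlation 0.01) over the brightest probe set of each locus, with an estimated correlation and fry beside it. Counts and adjusted p-values given for fry are those of its directional test. Its mixed test asks whether members change in either direction.

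The tests were tried on simulated arrays, 20 runs of 22746 probe sets with 200 changed. The 2 ways of drawing the spread gave different answers, and both are stated. With each probe set's SD set to the value limma estimated for it, 9.72% of the calls were false, and 92.0% of 1.5-fold and 99.9% of 2-fold changes were recovered. With variances drawn from the prior that limma fitted, 5.26% of the calls were false, and 56.4%, 98.4%, 99.9% and 99.8% of 1.5-, 2-, 3- and 4-fold changes were recovered. The second was written after the first had missed the nominal share of 5%. It draws from the model that the test assumes, so its false share is partly built in. A shift of 0.4 planted in the 47 UDP-glycosyltransferases was called under both, and 0 of the 52 lists sharing no member with it were. Each was a single draw in which probe sets varied independently. In the data the estimated inter-gene correlation was 0.512 for the plastid-encoded and 0.427 for the ATG8 list. How often the preset correlation calls unshifted but correlated lists was therefore not tried. The planted shift also exceeds the medians of the lists called in the data.

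Alternatives planned before the data were examined were quantile normalization, median centring, pseudocounts of 1 and 64, leaving out the dimmest 30% or 50% of probe sets, no intensity trend, robust estimation, replicate number as a block, leaving out each array, an adjusted p scaled by the share of unchanged probe sets, and fold thresholds.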

Results

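Transcript levels were measured in whole seedlings of *Arabidopsis thaliana* on Affymetrix ATH1 arrays, which hold one probe set or more for most protein-coding genes of this plant. The wild type was the accession Col, and the mutant was ref6-1 in the Col background. REF6, also called JMJ12, is a Jumonji-type demethylase that removes the repressive methyl marks of lysine 27 on histone H3. Seedlings of both genotypes were grown for 10 days on MS medium, a standard plant nutrient agar, at 23 °C with 16 h of light and 8 h of darkness. Each genotype was represented by 2 arrays, which the labels call biological replicates, so 4 arrays entered the comparison and their number limits the precision. The deposited values were intensities on a linear scale, and the 4 arrays had median intensities of 146.3 and 142.6 in Col and of 144.6 and 143.4 in ref6-1. The correlation of log2 intensities across probe sets was 0.994 between the Col arrays and 0.995 between the ref6-1 arrays, and it lay between 0.988 and 0.994 for pairs of different genotype. These correlations are across probe sets, which are not independent replicates.

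The comparison asked which transcripts differ in abundance between ref6-1 and wild-type seedlings. The most changed named gene was AT5G24240, whose intensity was 29.1 ± 2.38 (SD, n = 2) in Col and 308 ± 20.1 (SD, n = 2) in ref6-1, a log2 fold change of 2.84 (SE 0.105, limma adjusted p = 3.61e-06). At the other end AT3G60980 had 672 ± 49.1 in Col and 154 ± 12.4 in ref6-1, a log2 fold change of -2.02 (SE 0.105, adjusted p = 3.61e-05). Transcripts of ATG8B and ATG8G, members of the ubiquitin-like ATG8 family that coats autophagosomes, were lower in ref6-1, as were those of the plant defensin PDF1.2b and of the MADS-box factor AGL18. ICL, the isocitrate lyase of the glyoxylate cycle, was higher. In all, 337 of the 22746 probe sets tested passed an adjusted p of 0.05 in limma, 176 of them higher and 161 lower in ref6-1. In each of the 337, both ref6-1 arrays lay on the same side of both Col arrays. Selection by a small p with 2 arrays per genotype nearly requires this, so it is no separate support. Over all probe sets tested it was so for 35.6%, against 33.3% by chance. The count was 533 when Col replicate 2 was left out.

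**Figure D1:**
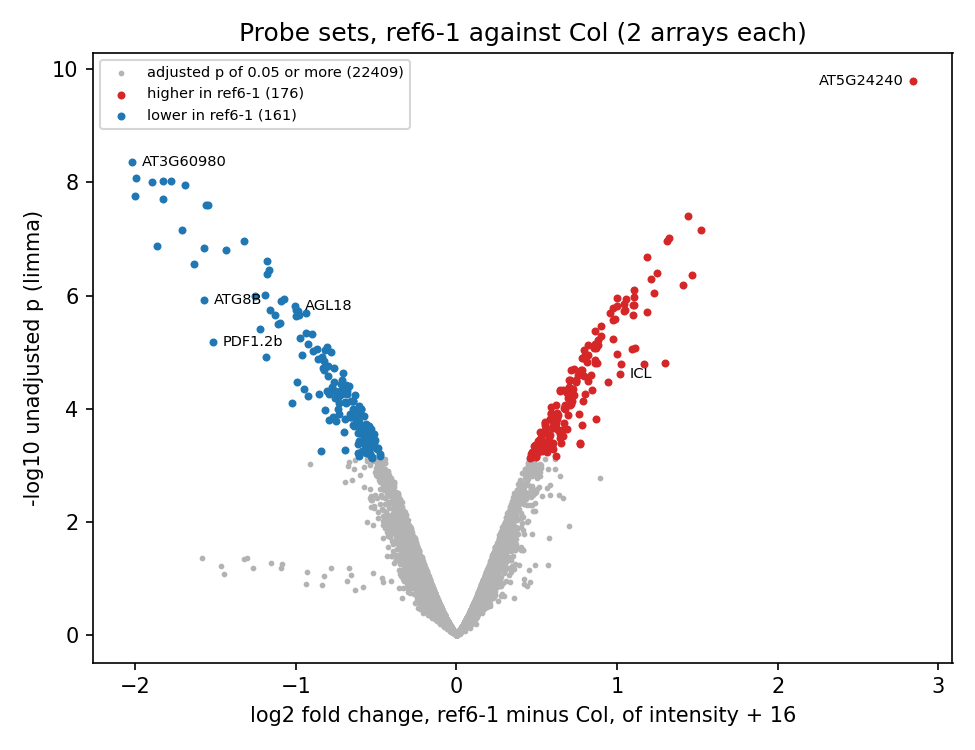
Each point is a probe set, with the log2 fold change of intensity + 16 (ref6-1 minus Col) on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis. The 176 probe sets higher in ref6-1 are red, the 161 lower ones are blue, and AT5G24240 lies apart from the others at a log2 fold change of 2.84.

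Changes were mostly moderate. Among the probe sets past the threshold, 29 were at least 2-fold higher and 33 at least 2-fold lower in ref6-1, on the scale of log2(intensity + 16), which understates the change of dim genes. The smallest changes that passed were 0.46 upward and -0.47 downward. Requiring in addition an absolute log2 fold change of 0.6 left 236 probe sets, 117 higher and 119 lower. The design text prints its fold threshold as 20.6, most probably 2 to the power 0.6 with its typography lost. Of the 22746 probe sets 0 reached a 20.6-fold change, either in the ratio of mean intensities, where the highest was 10.6 for AT5G24240, or on the scale of log2(intensity + 16), where the same gene read 7.18. An unadjusted limma p under 0.05 was found for 1933 probe sets, where 1137 would be expected by chance if no probe set differed.

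The transcript of REF6 itself was not analysed here, because no probe set carries that name in the annotation used, so the arrays were not checked against their genotype labels in this way. Of the 337 probe sets, 150 had a single named gene, 75 in each direction. The other 187 are not paired with a single gene in that annotation and entered the counts only.

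The 15 named genes with the highest fold changes ranged from 0.97 to 2.84 in log2, and most carry only a locus code. After AT5G24240 came AT4G29780 with a log2 fold change of 1.44 (SE 0.0948) and AT2G29500 with 1.33 (SE 0.0961). AT5G48570, also called FKBP65 or ROF2, a peptidyl-prolyl isomerase of the FKBP class, had the brightest probe set of this group, at 771 ± 39.9 in Col and 1939 ± 49.4 in ref6-1. AT4G27654 and AT4G27652, which are neighbours among the measured loci, had log2 fold changes of 1.30 (SE 0.165) and 1.17 (SE 0.149). AT3G10930, AT5G65300, AT5G17350, AT1G19320, AT3G53310 and AT5G51440 followed, with log2 fold changes between 1.02 and 1.23. ICL rose from 122 ± 9.23 to 266 ± 55.8, a log2 fold change of 1.02 (SE 0.137, adjusted p = 0.00489). AT2G34930 and AT1G52070 closed the group at 1.00 and 0.97.

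The 15 named genes with the lowest fold changes ranged from -2.02 to -1.0 in log2. AT2G07140 was read by a probe set of the x_at kind, which can detect several similar transcripts, and fell from 201 ± 28.4 in Col to 37.9 ± 3.95 in ref6-1. AT5G02540 had the brightest probe set of this group and fell from 1874 ± 178 to 517 ± 18.05, and AT1G65370 had a log2 fold change of -1.78 (SE 0.101). The log2 fold change was -1.57 (SE 0.149, adjusted p = 0.000706) for ATG8B and -1.18 (SE 0.147, adjusted p = 0.00302) for ATG8G. AT3G22750, AT5G39850, AT1G33970 and AT5G05710 lay between -1.57 and -1.43. AGL18, a MADS-box factor known as a repressor of flowering, fell from 210 ± 3.72 to 96.8 ± 3.21, a log2 fold change of -1.0 (SE 0.0983, adjusted p = 0.000798). AT3G04000, AT5G05180 and AT5G23750 were at -1.08, -1.02 and -1.0. The 15 highest and 15 lowest genes kept their direction and stayed past the adjusted threshold under those of 13 settings in which they were tested. Those settings do not include the fold thresholds. The genes were picked for extreme fold changes in the same arrays, so this is weak support.

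**Figure D2:**
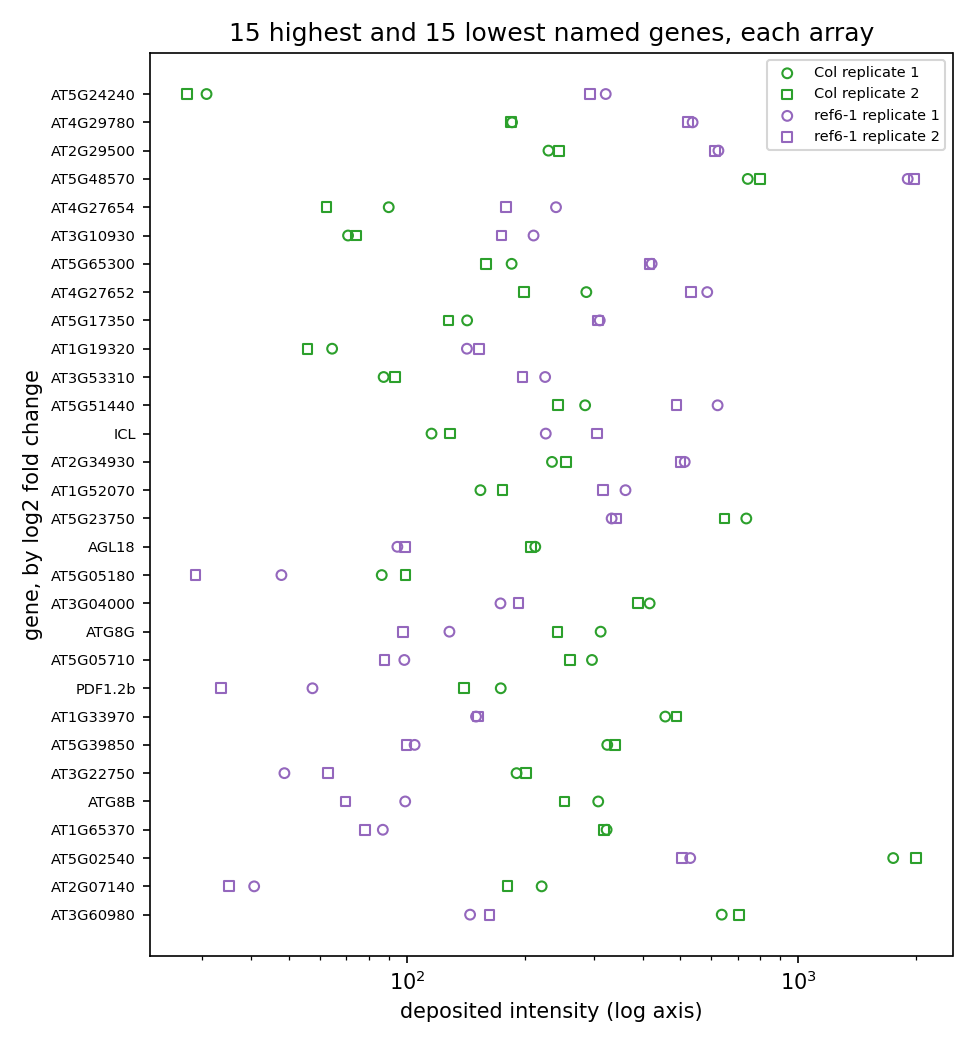
Deposited intensities on a log axis for the 15 named genes with the highest and the 15 with the lowest log2 fold change, with Col arrays in green and ref6-1 arrays in purple, circles for replicate 1 and squares for replicate 2. By the rule that picked these genes, both ref6-1 arrays lie to the same side of both Col arrays, as in AGL18, at 210 on average in Col and 96.8 in ref6-1.

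Among the genes of the 21 lists fixed before the data were examined, 28 of 268 members were named by the annotation used and no list had more than 4 of them, so no list could be tested as a group. Of the 28, none was called higher, 3 were lower and 25 did not pass over all probe sets. None of the 10 heat shock members is among the 28, and 2 of them were left out because code and symbol disagreed. The 3 lower ones were PDF1.2b of the jasmonate list, EXPA8 of the brassinosteroid response list and PPDK of the leaf senescence list. Adjusted over the list alone, none was higher and 7 were lower. That adjustment is light, since the lists had few named members, with EXPA8 alone in its list. It also does not cover the number of lists. PDF1.2b, a defensin gene induced by jasmonate and ethylene, had 157 ± 23.8 in Col and 45.4 ± 16.9 in ref6-1, a log2 fold change of -1.51 (SE 0.174, adjusted p = 0.00207). Its probe set is also of the x_at kind. The other defensin of that list, PDF1.2, had a log2 fold change of -0.47 with an adjusted p of 0.191 over all probe sets and 0.00588 adjusted over the list alone. Without Col replicate 2 it passed over all probe sets at -0.63 (adjusted p = 0.00871), whereas it had -0.30 without Col replicate 1 (adjusted p = 0.652) and -0.38 without ref6-1 replicate 2 (adjusted p = 0.770). EXPA8, a cell wall-loosening expansin, had a log2 fold change of -0.61 (SE 0.0985, adjusted p = 0.0142), and its adjusted p was 0.0618 without Col replicate 1. PPDK, the pyruvate orthophosphate dikinase, had a log2 fold change of -0.54 (SE 0.0946, adjusted p = 0.0202), and its adjusted p was 0.0690 without Col replicate 2.

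The other members of the fixed lists did not pass over all probe sets. Among the floral repressors the log2 fold change was 0.00 for both SMZ and SNZ, which encode AP2-type factors, with adjusted p of 0.998 for each. The floral promoters FD and AGL24 had log2 fold changes of -0.07 and -0.01. The auxin-related genes WES1, also called GH3.5, IAA29 and GH3.3 had values of -0.54, -0.29 and -0.20, with adjusted p of 0.115, 0.354 and 0.670 over all probe sets. WES1 and IAA29 were among the 7 lower ones adjusted over the list alone. WES1 passed over all probe sets without Col replicate 1 (limma adjusted p = 0.0184) and without ref6-1 replicate 2 (adjusted p = 0.0170). Among the histone demethylases other than REF6, AT3G45880, also called JMJ32, and LDL2 had -0.16 and -0.06. The clock-associated genes GI and COR27 had -0.04 and -0.39, and COR27 passed without Col replicate 2 (limma adjusted p = 0.0431). The cold-responsive genes LTI30, COR15B, COR15A and COR47 had 0.28, 0.24, 0.10 and -0.24. The leaf markers RCA and LHCB4.1 had 0.06 and 0.02, with RCA at -0.01 after quantile normalization, and the root markers EXPA7 and EXPA18 had 0.11 and 0.09. CLV3, WRKY53, DFR, UF3GT and BCAT4 lay between 0.03 and 0.27.

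Since the fixed lists could not be tested, 55 further lists of at least 5 genes were drawn from the gene names in the annotation, after the files had been seen and before any expression test. limma's camera with a preset inter-gene correlation of 0.01 called 3 of the 55 lists. None of the 3 was called with an estimated correlation, where the smallest adjusted p was 0.922. With 2 arrays per genotype that version has few residual degrees of freedom and could call little. For the UDP-glycosyltransferases the estimated correlation was -0.00683, below the preset value, yet the unadjusted camera p went from 0.000694 to 0.0547. Not passing that version therefore does not argue against a shift. The ATG8 list of 10 genes, 9 of the ATG8 family and the conjugating enzyme gene ATG3, had a median log2 fold change of -0.22 (adjusted p = 8.31e-06). This median was -0.10 without ref6-1 replicate 2 (adjusted p = 0.0335), -0.49 without ref6-1 replicate 1 and -0.37 without Col replicate 2. In it ATG8B and ATG8G passed the test as lower and 8 did not pass, and all 10 values were below 0, with ATG8D at -0.47 and ATG8H at -0.05. The 69 plastid-encoded genes had a median log2 fold change of 0.11 (adjusted p = 3.21e-06), with 61 values above 0 and none of the genes past the test on its own. The median of this list was -0.01 without Col replicate 1, and its adjusted p was then 0.802; without ref6-1 replicate 2 it was 0.231. The 47 UDP-glycosyltransferases, which attach sugars to hormones and secondary metabolites, had a median of 0.05 (adjusted p = 0.0127) and none passed on its own. Its adjusted p was 0.137 without Col replicate 1 and 0.210 without ref6-1 replicate 2. That median was 0.02 without ref6-1 replicate 2, 0.08 without Col replicate 2, and 0.11 without either the dimmest 30% or the dimmest 50% of probe sets. The list of 21 beta-glucosidases had a median of 0.08. With all arrays it was called only with those filters, at medians of 0.143 and 0.203 (camera adjusted p = 0.0137 and 0.00901). Its median was 0.109 without Col replicate 2 and 0.0502 without Col replicate 1. For each of these 4 lists the adjusted p with an estimated correlation was 0.922.

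**Figure D3:**
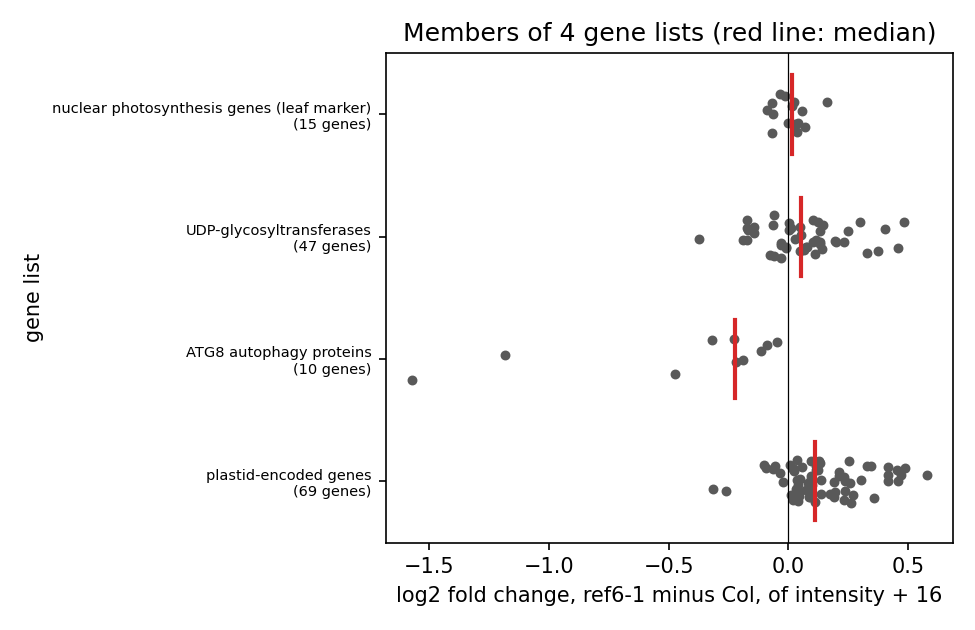
Log2 fold changes (ref6-1 minus Col, of intensity + 16) of the members of 4 gene lists, with 1 point per gene and the median of each list as a red line. ATG8B and ATG8G lie at -1.57 and -1.18, and the nuclear photosynthesis genes have a median of 0.02.

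The 5' and 3' control probe sets gave ratios that mark RNA integrity. The ratio of 3' to 5' intensity was 5.04 ± 0.0933 in Col and 4.87 ± 0.315 in ref6-1 for actin, and 2.5 ± 0.438 and 2.26 ± 0.185 for GAPDH (SD, n = 2 each). For ubiquitin it was 2.1 ± 0.0587 in Col and 1.98 ± 0.00636 in ref6-1, with the arrays of the genotypes apart. In a separate limma fit with the control probe sets included, 0 of the 64 passed, the smallest adjusted p over all 22810 probe sets being 0.652.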

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

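Of the 32 named genes past the threshold, 30 kept their direction and their side of it under all 13 settings in which they were tested. These 30 had been picked for the largest fold changes in the same arrays, so this was likely in advance. EXPA8 and PPDK each lost the call without 1 Col array. WES1 gained it without Col replicate 1 and without ref6-1 replicate 2, and PDF1.2 and COR27 gained it without Col replicate 2. The count of 337 probe sets (176 higher, 161 lower) lay between 272 and 378 under normalization, pseudocount, filter and prior alternatives, and 315 of the 337 stayed called in the same direction after quantile normalization. Leaving out 1 array in turn, with a lone array assumed to vary like the other genotype, gave 273 to 533 probe sets, 143 to 238 higher and 130 to 295 lower (533 without Col replicate 2); 258 and 291 of the 337 stayed called without Col replicates 1 and 2, and 272 and 245 without ref6-1 replicates 1 and 2. A log2 fold of at least 0.6 left 117 higher; a fold of at least 20.6 left 0, 0 and 0; and limma's treat against 0.6, which asks whether the change exceeds that size, left 25, with 8 higher and 17 lower. With replicate number as a block, 1636 probe sets were called, 790 higher and 846 lower. The labels give the 2 replicate numbers no shared batch, and with 2 pairs the correlation across probe sets of the replicate differences (0.279) does not establish a pairing, so the blocked count is given here alone; WES1, IAA29, PDF1.2, COR27, COR47 and LTI30 were also called under it.

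The 3 added gene lists became 4 without the dimmest 30% of probe sets and 5 without the dimmest 50%, 4 with the block, 0 with an estimated correlation and 0 with fry (at an unadjusted p under 0.05, camera had 10 and fry 3), and 1 to 7 when 1 array was left out; the cause was not tested. These alternatives on the added lists were chosen after seeing the files. When 1 array was left out, the ATG8 list's median went from -0.487 to -0.102 and the plastid list's from -0.0149 (without Col replicate 1) to 0.264. That of defensins and thionins went from -0.280 to 0.0242. The ATG8 list was not called with an estimated correlation (camera adjusted p = 0.922), a version that could call little with 4 arrays. Nor was it called with fry (adjusted p = 0.565). Genes not past the threshold that changed sign when 1 array was left out ranged from -0.11 to 0.11 for SNZ, -0.11 to 0.11 for SMZ, -0.224 to 0.0780 for FD, -0.0703 to 0.0451 for AGL24, -0.204 to 0.0920 for LDL2, -0.0552 to 0.0875 for LHCB4.1, -0.0320 to 0.0979 for UF3GT and -0.0113 to 0.137 for BCAT4; others kept their sign but moved, among them AT3G45880 (-0.278 to -0.0508), EXPA18 (0.00295 to 0.178), EXPA7 (0.0396 to 0.187), WRKY53 (0.0288 to 0.161) and DFR (0.164 to 0.370). RCA was at -0.00670 after quantile normalization. The REF6 transcript and the fixed gene lists have no values, and camera takes no robust prior, so these were not run. The unstated background correction limits what the dimmest probe sets can show.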

Other observations

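Except for the test of the mitochondrial genes and the count of neighbouring pairs with probe sets of several transcripts, the tests of explanations and hypotheses in this part were chosen or given their final bounds after related results had been seen. So were the genes singled out in the next paragraph and the comparison of single arrays after it. The limma calls and main camera results quoted in the next paragraph come from tests set before any expression test.

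Some other named genes past the limma threshold, picked by hand from the 150 with a single gene, are given as single values. ATHSP22.0, a small heat shock protein gene, had a log2 fold change of 0.78 (adjusted p = 0.00426), and Hop3, which encodes a co-chaperone, had 0.59 (adjusted p = 0.0121). The fixed heat shock list holds a gene HSP22.0, whose name differs from ATHSP22.0 only in the prefix. Of that list, 2 members were left out because code and symbol disagreed. None of its 10 members was among the 28 named, so ATHSP22.0 was not counted there even if it is the same gene. The absence of higher calls among those 28 thus says nothing about heat shock genes. The zinc finger gene STZ had 0.71 (adjusted p = 0.00426), the calmodulin-like genes CML37 and CML23 had 0.57 and 0.49 (adjusted p = 0.0327 and 0.0494), and the glucosinolate transporter gene GTR1 had 0.64 (adjusted p = 0.0282). On the lower side XTH33, a cell wall xyloglucan enzyme gene, had -0.72 (adjusted p = 0.00748) and the kinase gene WNK7 had -0.80 (adjusted p = 0.00379). Each of these was higher or lower in both ref6-1 arrays than in both Col arrays, as was every probe set past the threshold. With all arrays and no block, no test for a shift of a list in a single direction stands behind them. The lists of 7 calmodulin-like proteins, 8 glucosinolate genes and 9 xyloglucan enzymes were not called. They had 3 values above 0 and 4 below, 6 and 2, and 5 and 4. Nor was that of 13 cold and dehydration responsive genes that holds STZ (camera adjusted p = 0.424, 7 values above 0 and 6 below). The mixed test of fry, which counts changes in either direction, gave these lists in the same order unadjusted p of 0.0154, 0.0132, 0.00894 and 0.000961. These p-values were not adjusted over the lists, and the lists include genes singled out above. The glucosinolate list was called without Col replicate 2 (adjusted p = 0.0308), without ref6-1 replicate 1 (0.0446) and with a replicate block (0.0374), but not without Col replicate 1 (0.726), without ref6-1 replicate 2 (0.231), with an estimated correlation (0.922) or with fry (0.565).

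In 13 probe sets Col replicate 1 was at least 3-fold brighter than each of the other 3 arrays on the log2(intensity + 16) scale, and no other array stood apart in this way in any probe set, brighter or dimmer. AT1G06340 read 530 in Col replicate 1 and 39.5, 54.2 and 42.3 in the other arrays. AT5G66150 read 361 against 31.4, 29.6 and 27.6, and AT5G48640 read 993 against 189, 183 and 193.

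The split of the 4 arrays by genotype called 337 probe sets and the highest of the other splits called 0. Each other split has 1 array of each genotype in both groups, so any genotype difference widens the spread within groups. The 0 is therefore not a count of calls expected by chance. Only 3 splits exist, of which 1 gave as many, which is too few for a share under 0.05. Quantile normalization moved the log2 fold of any probe set by at most 0.0641 and of a called probe set by at most 0.0449. The smallest called change was 0.458 in size. These values argue against scale differences shared across a whole array and left in the deposited values, and cover no other kind. The arrays were already nearly alike, and any effect of scaling before deposit was not tested. RNA integrity stays open: the ratios of 3' to 5' control signal lay apart between genotypes for 1 of 3 control transcripts, ubiquitin, by 2.90 pooled SDs, where chance sets 33.3% apart. Actin and GAPDH differed by 0.727 and 0.697 pooled SDs, and the GAPDH ratios of the Col arrays, 2.806 and 2.187, lay farther from each other than the genotype means. The effect of the genotype itself stays open beside it, untested, and growth or harvest differences between the genotypes' plates are not given in the labels.

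The plastid-encoded genes had a median shift of 0.11, but over the same genes replicate 2 exceeded replicate 1 by a median of 0.28 in Col and of 0.18 in ref6-1. The difference between genotypes is thus smaller than that between replicates, consistent with array or RNA differences that also separate replicates. The nuclear photosynthesis genes, markers of green tissue, had a median of 0.02 (0.0161, bootstrap 95% bounds -0.0364 and 0.0395), an upper bound below the plastid shift. The 11 chlorophyll and haem biosynthesis genes instead had a median of 0.08, with 9 values above 0 (camera adjusted p = 0.193). Their median also depended on single arrays, at 0.0314 without Col replicate 1 and 0.137 without Col replicate 2. These lists point to different answers, so a larger share of green tissue stays open. The 11 mitochondrially encoded genes had a median of -0.0444 (bounds -0.125 and 0.0515), so they did not share the upward shift. Their median replicate difference in Col, -0.0854, was larger in size, so a larger share of all organellar RNA is not excluded. Genes are not independent in these intervals, which resample genes and leave out the spread between arrays. Leaving out single arrays moved the plastid median from -0.0149 to 0.264.

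A hypothesis that called genes lie next to each other was tested on 13217 nuclear loci, of which 148 were called. There were 2 pairs of neighbouring measured loci called in the same direction, AT4G27652 with AT4G27654 and AT1G72920 with AT1G72940, all higher in ref6-1, and 1 pair called in opposite directions. Random placements of the calls gave a median of 1 pair, and 2 or more in a share of 0.194 (permutation test, one-sided, 10000 placements), so no clustering was detected. The bound first set counted such a p as evidence against clustering; it was replaced after the result was seen, because a p that misses the threshold with 1 pair expected excludes little. Of the 2 pairs, 0 held a probe set marked as detecting several transcripts.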
